A study of Mus musculus with 3 samples.

How the data were processed

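Single-cell RNA sequencing was done on mouse (C57BL/6) organoids grown from Lgr5-positive cochlear progenitor cells, in 3 groups with 1 library each: expansion medium (passage 2, day 8), day 5 and day 25 of differentiation. Per the labels' protocols, expansion medium held the growth factors EGF, bFGF and IGF at 20, 10 and 50 ng/mL and the compounds CHIR99021, Y-27632 and LPA at 3, 10 and 2.5 (unit written as um), and differentiation medium held bFGF, BDNF, Shh, A83-01, RA and, until day 5, LY4115775. Organoids were treated with 0.125% trypsin for 25 min, stained with DAPI and sorted for single living cells, and libraries were made with 10x Genomics Single Cell 3' v3 chemistry.

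The deposited matrices held raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger, version 3.0.1 for expansion and day 5 and 3.1.0 for day 25 per the file headers. The submitters' processing notes name the builds GRCm38 and hg38; the gene table held 31053 mouse Ensembl IDs, of which 30934 were matched to a GRCm38 position. The annotation release and the settings of cell calling are not stated in the sources used here. The lowest barcode held 657 UMIs in expansion and 500 on days 5 and 25, and the matrices held 207026905, 140255047 and 76296949 UMIs with medians of 4778, 5803 and 8310 per barcode.

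Barcodes with fewer than 500 genes (935, 550 and 120) or with more than 20% mitochondrial UMIs (311, 100 and 264) were left out. Doublets were called in each library against simulated doublets (1500 variable genes, 30 principal components, threshold at the minimum of the histogram of simulated scores), at an expected 0.8% per 1000 barcodes. Called doublets were 10.02%, 4.24% and 1.93% of passed barcodes against an expected 22.4%, 11.1% and 5.01%, so doublets remain. UMIs were summed over kept cells, and CPM were taken over all genes. Exact Poisson intervals give the counting error of each sum, and 3 UMIs served as floor for a gene with 0 counts (0.0174, 0.0228 and 0.0411 CPM). Intervals and floors cover counting error only.

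Genes with at least 20 CPM in either library of a pair were counted as higher or lower from a 2-fold difference of CPM + 1; mitochondrially encoded genes were left out of the counts of genes. For 17 cell type lists and 24 process lists, written before the data were examined, the median log2 ratio of members with at least 5 CPM was taken where at least 5 were measured, and set against 10000 random lists matched on expression in 20 bins; 200 Poisson redraws gave its counting range. Named genes were the 12 with the largest difference in each direction, leaving out ribosomal protein genes, mitochondrial genes and unnamed models, the 2 to 4 list members with the largest differences, and a fixed set of markers. For classes of cells they were the 8 largest in each direction with at least 50 CPM and the bundle, synapse and maturation genes. The text names some of these genes, chosen with their values seen, and a few genes that this rule covers are not reported here. The symbols Ccn1 and Ccn2 were listed under their older names Cyr61 and Ctgf.

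All kept cells were clustered together without integration (10000 UMIs per cell, log scale, 2000 variable genes chosen within each library, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster took the name of a list when at least 3 of its markers were 4-fold over all other cells and at 20 CPM or more, no list had a larger share of such markers, and its leading 10 genes held no more markers of another list; clusters of low depth also needed a marker of their own among those genes. This rule was completed after the clusters had been seen. The Pou3f4-high background class (at least 100 CPM Pou3f4, Epcam at most 25% of the library level) was also chosen after the data were seen. Hair cell-like and Pou3f4-high cells, with at least 30 cells in both libraries of a pair, were compared, and other classes past that number were not. Shares of cells have exact Clopper-Pearson 95% intervals. Shares of cells with a marker UMI or in S or G2/M were taken after thinning cells to 2000 UMIs, with shallower cells left out. Shares of classes, and of cells with a defensin UMI, were taken over kept cells without thinning.

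No test between groups was run, since each group held 1 library. Simulated data, in which 200 genes were changed, were used to check the counting: all 67 genes at 3-fold and all 66 at 5-fold were past 2-fold in each comparison, and 0 of 67 genes at 1.5-fold. The simulated libraries differed by counting error and the changed genes only, and those genes had mean levels above the 20 CPM bound. The simulation therefore does not cover scaling, differences between libraries or genes with few UMIs. Of 200 unchanged random lists, 12, 9, 6 and 6 lay outside the central 95% in the 4 comparisons run. Alternatives tried were TMM and median of ratios scaling, a pseudocount of 5 CPM, no filter on low levels beyond 1 CPM, doublets kept, at most 10% mitochondrial UMIs, all deposited barcodes, equal weight for each cell, thinning to 1000 UMIs or none, at least 5 UMIs for a phase call, and clustering at resolutions 0.5 and 2 or within each library. Tools were Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.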

Results

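Single-cell transcriptomes were collected from mouse cochlear organoids, which are clusters grown in culture from cochlear progenitor cells that carry the surface receptor Lgr5. The 3 groups were organoids in expansion medium (passage 2, day 8), organoids on day 5 of differentiation and organoids on day 25 of differentiation, with 1 library in each. The deposited matrices held 29098 barcodes for expansion, 14452 for day 5 and 6613 for day 25. After filtering and removal of called doublets, 25190, 13263 and 6143 cells were kept, with 172116753, 131579289 and 72957262 transcript counts (unique molecular identifiers, UMIs) in all. The median kept cell held 4558 UMIs and 1629 genes in expansion, 5832 UMIs and 2184 genes on day 5, and 8482 UMIs and 3051 genes on day 25. Levels are in CPM, the usual scaling of summed UMIs of all kept cells to a common library total, and folds are ratios of CPM. Since each group was a single library, no test between groups was possible and no p-value or standard error is given; the 95% intervals cover counting error only, and group and library cannot be separated. Genes are called higher or lower from a 2-fold difference of CPM + 1. A list median is the median log2 ratio of the list's measured members, set where useful beside the central 95% of random lists of matched expression.

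Day 5 against expansion asked how the organoids differed after the move from medium for growth to medium for differentiation. Most S phase, G2/M and Wnt target genes were lower on day 5, while most hair cell, greater epithelial ridge, tectorial and otoconial matrix, and stress and immediate early genes were higher. Clu, which encodes the secreted chaperone clusterin, stood at 6596 CPM on day 5 and 38.5 CPM in expansion, a 171-fold difference (167 to 175; ENSMUSG00000022037, chromosome 14, 65968483 to 65981547 in GRCm38). Mki67, a marker of dividing cells, was at 2.11 CPM on day 5 and 122 CPM in expansion, 57.8-fold lower (51.4 to 65.3). Of 6416 genes with at least 20 CPM in either library, 984 were higher and 501 lower on day 5.

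Besides Clu, the 12 genes with the largest differences toward day 5 included Spp1, the gene of the secreted phosphoprotein osteopontin (268 against 1.55 CPM), the growth factor gene Igf1 (156 against 0.965 CPM) and the chemokine gene Ccl2 (95.3 against 0.0872 CPM, 1094-fold, 663 to 1955). Tecta, which encodes the tectorial membrane protein alpha-tectorin, was 45.0-fold higher and reached 891 CPM. Calb1, encoding a calcium-binding protein of hair cells and their neighbours, was 93.0-fold higher. Rasgrf1 was 560-fold, Bgn 183-fold, Wfdc18 128-fold, Cited1 128-fold and Rgcc 120-fold higher. At the other end stood the serine protease gene Prss56 (1.48 against 269.8 CPM, 182-fold lower), the Wnt antagonist gene Dkk2 (203-fold lower), the receptor kinase gene Ret (137-fold lower), Anks1b (167-fold lower), Bpifb5 (133-fold lower) and the cornified envelope gene Ivl (269-fold lower). The cell division genes Pclaf, Top2a and Ube2c were 73.9-fold, 44.0-fold and 51.5-fold lower.

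Among cell type lists, 17 of 19 measured hair cell genes were higher on day 5 and none lower, with a median log2 ratio of 2.35 against a random range of -0.14 to 0.86. Acbd7 was 19.0-fold, Pcp4 15.02-fold and Tomt 16.9-fold higher. Otof, which encodes the calcium sensor otoferlin of the hair cell synapse, was 16.8-fold higher (14.6 to 19.4), and the hair cell transcription factor gene Pou4f3 stood at 22.1 against 3.54 CPM, 6.24-fold higher (5.72 to 6.82). Atoh1, the factor that starts hair cell formation, was at 3.27 against 1.93 CPM, 1.69-fold apart. Greater epithelial ridge genes (12 of 14 higher and 2 lower, median 2.49) included Epyc, at 1824 against 88.5 CPM, and Fst, 77.01-fold higher. Lateral epithelium genes were mostly higher (6 of 8, median 2.07), with Gata3 at 555 against 72.7 CPM and Gata2 29.9-fold higher, while Lgr6 was 5.62-fold lower. Of 15 supporting cell genes, 9 were higher and 3 lower. Sox2, a factor of prosensory and supporting cells, was 12.5-fold higher (11.5 to 13.7), whereas the progenitor receptor gene Lgr5 was 12.6-fold lower (11.5 to 13.8) and the Notch ligand gene Jag1 16.8-fold lower. Mesenchyme genes were higher in 8 of 10 cases (median 1.67), with Postn 149-fold and Col1a2 116-fold higher. Multiciliated cell genes were higher in 4 of 5 cases, and glial genes in 2 of 6; stria marginal cell genes split 3 higher to 2 lower of 5, and epithelial genes 2 to 1 of 8. In lists with too few members for a median, all 4 measured neuronal genes were higher (Gap43 31.1-fold, Syt1 14.7-fold), 1 of 2 pericyte and 1 of 2 melanocyte genes were higher, and the single measured squamous and secretory genes were higher. None of 3 endothelial genes differed by 2-fold, and no macrophage or erythroid gene was measured.

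None of the 42 measured S phase genes and none of the 51 G2/M genes was higher on day 5, while 38 and 45 were lower, with medians of -2.20 and -3.48. Rrm2 was 31.1-fold and Birc5 37.9-fold lower. Among cell cycle inhibitors, Cdkn1c was at 634 against 163 CPM, Btg2 was 13.3-fold higher and Cdkn1b 2.51-fold higher, while Cdkn2c was 7.74-fold lower. Wnt targets were lower in 10 of 14 cases and higher in 1 (median -1.98); Axin2 was 3.70-fold (3.58 to 3.83), Sp5 9.79-fold and Ccnd1 8.52-fold lower. TGF-beta targets were higher in 10 of 11 cases (median 2.33), among them Smad7, which encodes an inhibitor of that pathway, at 146 against 13.2 CPM. YAP targets were higher in 6 of 9 cases (Cyr61 22.1-fold, Ctgf 7.12-fold). Of 12 FGF and ERK targets, 1 was higher and 4 were lower, among them Etv4 (3.71-fold) and Phlda1 (3.996-fold). Notch genes split 4 higher to 2 lower of 11, retinoic acid response genes 3 to 2 of 8, and 2 of 4 Hedgehog targets were higher. Ptch1 was at 9.52 against 7.18 CPM, and Gli1 had 2 UMIs against 1. Hair bundle genes were higher in 12 of 18 cases (Xirp2 45.1-fold, Ptprq 21.0-fold), hair cell synapse genes in 5 of 7, hair cell maturation genes in 6 of 8 and tectorial and otoconial matrix genes in 9 of 12, where Col2a1 stood at 1426 CPM, 11.1-fold higher. Glycolysis and hypoxia genes were lower in 10 of 16 cases and higher in 1 (Pgk1 5.09-fold, Pkm 4.09-fold) and cholesterol synthesis genes in 10 of 17 (Dhcr7 3.23-fold). All 6 measured MHC class I genes were higher (H2-D1 7.81-fold, H2-K1 4.12-fold). Stress and immediate early genes were higher in 11 of 12 cases (median 2.32), with Fos at 1603 against 175 CPM and Junb at 1033 against 85.5 CPM. The unfolded protein response list had 4 of 9 higher (Hspa5 2.24-fold), matrix and basement membrane genes 6 of 13 higher, and inner ear progenitor factors 4 of 11, with Id3 at 2464 against 502 CPM. Of the p53 targets 1 of 11 was higher, of the antioxidant genes 1 of 9, and of the interferon genes 2 of 3, with Ifitm3 2.79-fold higher and Bst2 2.36-fold lower.

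Total count scaling set the median of all 6416 genes at 0.18. Ribosomal protein transcripts made up 31.6% of UMIs in expansion, 21.8% on day 5 and 14.5% on day 25. With TMM scaling that median was -0.18 and 636 genes were higher against 934 lower, and with median of ratios scaling 619 were higher against 961 lower. The medians of the stria marginal, epithelial, retinoic acid and p53 lists changed sign with TMM scaling, so only counts of their members are given. Counts of members of all lists were taken with total count scaling only and depend on it too.

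Day 25 against day 5 compared late with early differentiation, that is, organoids at the end of the days with LY4115775 (the labels' spelling; taken here for a gamma-secretase inhibitor, which blocks Notch signalling) and organoids cultured on without it. Most hair cell, bundle, synapse and maturation genes were higher on day 25, together with 6 of 9 epithelial genes, whereas 5 of 10 mesenchyme genes were lower. Ocm, which encodes oncomodulin, a calcium buffer of outer hair cells, was at 765 CPM on day 25 and 3.03 CPM on day 5, 252-fold higher (229 to 279; ENSMUSG00000029618, chromosome 5, 144019804 to 144026670). Slc26a5, the gene of the outer hair cell motor protein prestin, had 97.7 CPM against 3 UMIs in all, a ratio of 4286 with a counting interval of 1466 to 20789.8. Of 7183 genes, 1518 were higher and 415 lower on day 25.

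Other genes among the 12 with the largest differences toward day 25 were Vmo1 (357-fold), Lce6a (478-fold), Cdh13 (133-fold), the chemokine gene Cxcl10 (88.7 against 0.0836 CPM), the interferon-induced gene Ifit1 (281-fold), the tight junction gene Cldn4 (101-fold), the antioxidant gene Srxn1 (86.4-fold), Sprr1a (86.6-fold) and the keratin genes Krt8 (67.8-fold, 64.6 to 71.1) and Krt18 (51.5-fold). In the opposite direction, Col2a1, encoding the collagen of cartilage and the tectorial membrane, was 17.8-fold lower (17.3 to 18.3). Otor, expressed by cochlear mesenchyme, was at 267 against 2151 CPM. The growth-associated gene Gap43 was 17.5-fold, the heparin-binding factor gene Mdk 9.65-fold, Mfap2 11.8-fold, Col3a1 9.08-fold, Bmf 13.4-fold and the Wnt inhibitor gene Wif1 9.22-fold lower.

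Hair cell genes were higher on day 25 in 20 of 23 cases and lower in 1 (median 1.92). Pou4f3 reached 205 CPM, 9.28-fold higher (8.92 to 9.66), Calb2 was 17.1-fold, Chrna9 48.5-fold and Gfi1 7.97-fold higher, and Otof was 3.89-fold higher (3.71 to 4.07). Atoh1 was nearly level, at 3.56 against 3.27 CPM (1.09-fold, 0.931 to 1.28). Bundle genes were higher in 25 of 27 cases (median 2.16), among them the mechanotransduction channel gene Tmc1 (52.7 against 0.540 CPM, 97.6-fold), Ptprq (24.3-fold) and Loxhd1 (22.4-fold). Synapse genes were higher in 9 of 12 cases, with Slc17a8, the vesicular glutamate transporter gene, 46.5-fold and Cabp2 15.6-fold higher. Maturation genes were higher in 13 of 16 cases, with a median of 3.11. Like all comparisons of whole libraries, these sums depend on how many cells of a kind each library held. Hair cell-like cells, described below, were 1.64% of day 5 cells and 28.7% of day 25 cells. Within that class the hair cell median was -0.77, the bundle median 0.08, the synapse median 0.32 and the maturation median 1.54. Epithelial genes were higher in 6 of 9 cases (median 1.86), with Epcam at 3540 against 973 CPM and Cdh1 4.16-fold higher, and 4 of 6 neuronal genes were higher and 1 lower, with Nefm (20.2-fold) and Snap25 (18.7-fold). Supporting cell genes split 6 higher to 3 lower of 16: Lgr5 was at 14.995 against 3.63 CPM, 4.13-fold higher (3.70 to 4.61), Fgfr3 6.92-fold and S100a1 4.74-fold higher, and Sox2 was at 34.5 against 41.7 CPM. Greater epithelial ridge genes split 4 to 4 of 14, with Calb1 7.74-fold and Tectb 10.99-fold higher and Crabp1 39.0-fold lower. Lateral epithelium genes split 2 to 2 of 9, with Gata3 3.32-fold and Bmp4 3.22-fold lower. Mesenchyme genes were lower in 5 of 10 cases and higher in 1 (median -1.11), with Pou3f4, a factor of otic mesenchyme, at 15.9 against 76.3 CPM. Endothelial genes were lower in 2 of 3 cases (Kdr 20.6-fold, Emcn 3.47-fold) and higher in 1, and glial genes were lower in 1 of 6. Multiciliated cell genes split 2 to 1 of 7 and pericyte genes 1 to 1 of 4. Of stria marginal genes 1 of 4 was higher, of melanocyte genes 1 of 2, of squamous genes 2 of 2, and the single measured secretory gene, Lcn2, was 27.5-fold higher.

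Cell division genes were low on both days: Mki67 was at 2.23 against 2.11 CPM. The S phase median was -0.33 (3 of 25 lower) and the G2/M median -0.37 (3 of 23 higher, 2 lower); without the Pou3f4-high cells described with the shares, these medians were 0.0093 and 0.045. Among inhibitors, Cdkn1c was 6.85-fold lower and Cdkn1a, a p53 target, 4.88-fold higher. Wnt targets split, with Sp5 12.3-fold lower, Myc 9.85-fold and Ccnd1 4.16-fold higher; 6 of 14 were lower and 3 higher, and the median of -0.47 was 0.24 without the Pou3f4-high cells. Notch genes were higher in 4 of 12 cases (Dll1 23.3-fold, Jag1 3.83-fold) and Nrarp, a target of the pathway, was 8.20-fold lower. Retinoic acid response genes were higher in 3 of 8 cases (Dhrs3 2.83-fold), and Cyp26b1 was 2.16-fold lower. Boc was the single Hedgehog list member of 4 to differ (2.63-fold lower). TGF-beta targets split 4 higher to 2 lower of 12, with Tgfbi 4.14-fold lower. FGF and ERK targets were higher in 6 of 14 cases and lower in 1, with the higher genes including Fosl1, at 47.7 against 0.418 CPM, and Spry2 (3.85-fold). YAP targets were higher in 4 of 9 cases (F3 26.0-fold). The stress and immediate early list had 5 of 13 higher, with Atf3 at 1040 against 48.1 CPM. The unfolded protein response had 5 of 10 higher (Chac1 14.8-fold, Ddit3 4.08-fold) and the p53 targets 6 of 11 (Trp53inp1 5.53-fold, Mdm2 2.46-fold). Cholesterol synthesis genes split 6 higher (Insig1 4.58-fold) to 1 lower of 17, and glycolysis and hypoxia genes 5 higher (Slc2a1 7.47-fold) to 1 lower of 17. Tectorial and otoconial matrix genes split 3 to 4 of 12, with Otol1 5.26-fold higher. MHC class I genes were higher in 2 of 7 cases, interferon genes in 2 of 4, with 1 lower, and antioxidant genes in 3 of 11, with Hmox1 4.72-fold higher. Of matrix and basement membrane genes 1 of 12 was lower (Nid2, 2.20-fold), and of progenitor factors 3 of 10, with Id3 4.87-fold lower and 1 higher.

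With total count scaling the median of all 7183 genes was 0.31. TMM scaling put it at 0.01, with 915 genes higher and 774 lower, and median of ratios scaling gave 984 higher and 699 lower.

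Day 25 against expansion spanned the whole course of differentiation. Most hair cell, bundle, synapse and maturation genes were higher on day 25, and most S phase, G2/M and Wnt target genes were lower. Pou4f3 was at 205 against 3.54 CPM, 57.9-fold higher (53.4 to 62.9). Prss56, at the other end, was at 0.137 against 269.8 CPM, 1968-fold lower (1070.1 to 4104). Of 7284 genes, 2440 were higher and 665 lower; the median of all genes was 0.51, and -0.19 with TMM scaling, which gave 1234 higher and 1608 lower, while median of ratios scaling gave 1275 and 1565.

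Ocm had 1 UMI in expansion, a ratio of 131746 with a counting interval of 23645 to 5203800, and Slc26a5 had none, which makes its level of 97.7 CPM on day 25 at least 5607-fold higher. The secreted protein gene Lcn2, with 2 UMIs in expansion, had a ratio of 17879 (4949 to 147644). Spp1 was 754-fold, Calb1 720-fold, the potassium channel gene Kcna10 1141-fold, Cdh13 3089-fold, Ptprq 509-fold, Smpx 209-fold, Ahnak 247-fold and Clu 187-fold higher. The genes with the largest differences toward expansion included genes of cell division (Ube2c 183-fold, Pclaf 226-fold, Pbk 198-fold, Birc5 115-fold, Cdca3 125-fold and Top2a 93.1-fold lower), with Ret 184-fold, Fam178b 222-fold and the Wnt target Sp5 120-fold lower.

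All but 1 of 23 hair cell genes were higher (median 4.35), as were 26 of 27 bundle genes (median 3.83; Grxcr2 408-fold, Xirp2 465-fold), 11 of 12 synapse genes (median 3.64; Slc17a8 255-fold) and 14 of 16 maturation genes (median 4.91; Strip2 335-fold). Gfi1 was 52.7-fold, Acbd7 53.02-fold and Pcp4 47.8-fold higher, against 1.85-fold for Atoh1. Greater epithelial ridge genes were higher in 11 of 13 cases (median 3.16; Fst 118-fold, Tectb 64.6-fold), lateral epithelium genes in 7 of 9 (Lmo3 148-fold), supporting cell genes in 9 of 15 with 2 lower (Fgfr3 80.1-fold and Sox2 10.4-fold higher) and epithelial genes in 8 of 9 (Krt8 49.5-fold, Epcam 5.56-fold). Lgr5 was 3.05-fold lower (2.86 to 3.25) and Jag1 4.39-fold lower. All 6 multiciliated and all 5 neuronal genes were higher (Stmn2 308-fold, Nefm 156-fold), as were 3 of 5 stria marginal genes, with Lrp2 132-fold higher and 1 gene lower, 2 of 2 melanocyte and 2 of 2 squamous genes, and 3 of 4 pericyte genes. The mesenchyme list split 3 to 1 of 9, glia 1 to 1 of 6 and endothelium 1 to 1 of 2.

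Of S phase genes 36 of 42, and of G2/M genes 44 of 51, were lower (medians -2.73 and -3.40), with Mki67 54.5-fold lower (46.7 to 63.95). Wnt targets were lower in 11 of 14 cases and higher in 1 (median -2.34), with Notum 20.6-fold, Nkd1 10.7-fold and Axin2 5.58-fold lower. Cell cycle inhibitors were higher in 7 of 10 cases, with Btg2 28.4-fold and Cdkn1b 4.25-fold higher. TGF-beta targets were higher in 10 of 12 cases (median 3.12; Ltbp2 29.2-fold), YAP targets in 5 of 9 (F3 104-fold, Cyr61 66.9-fold), stress and immediate early genes in 12 of 13 (median 3.39; Atf3 76.0-fold), all 7 MHC class I genes (H2-D1 22.2-fold), unfolded protein response genes in 7 of 10 (Chac1 47.1-fold), p53 targets in 6 of 11 (Trp53inp1 7.60-fold), interferon genes in 3 of 4 and antioxidant genes in 5 of 11 (Srxn1 142-fold). Glycolysis and hypoxia genes were lower in 10 of 17 cases and higher in 3 (median -1.24; Pgk1 6.46-fold) and cholesterol synthesis genes in 6 of 17 (Mvd 6.49-fold). Notch genes split 4 to 1 of 11, FGF and ERK targets 4 to 1 of 14 and retinoic acid response genes 3 to 2 of 8, with Crabp2 11.1-fold higher. Hedgehog targets were higher in 2 of 4 cases, with Boc 2.85-fold higher. Tectorial and otoconial matrix genes were higher in 6 of 12 cases, matrix and basement membrane genes in 4 of 12, with Lama1 32.8-fold lower, and progenitor factors in 4 of 11.

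**Figure D1:**
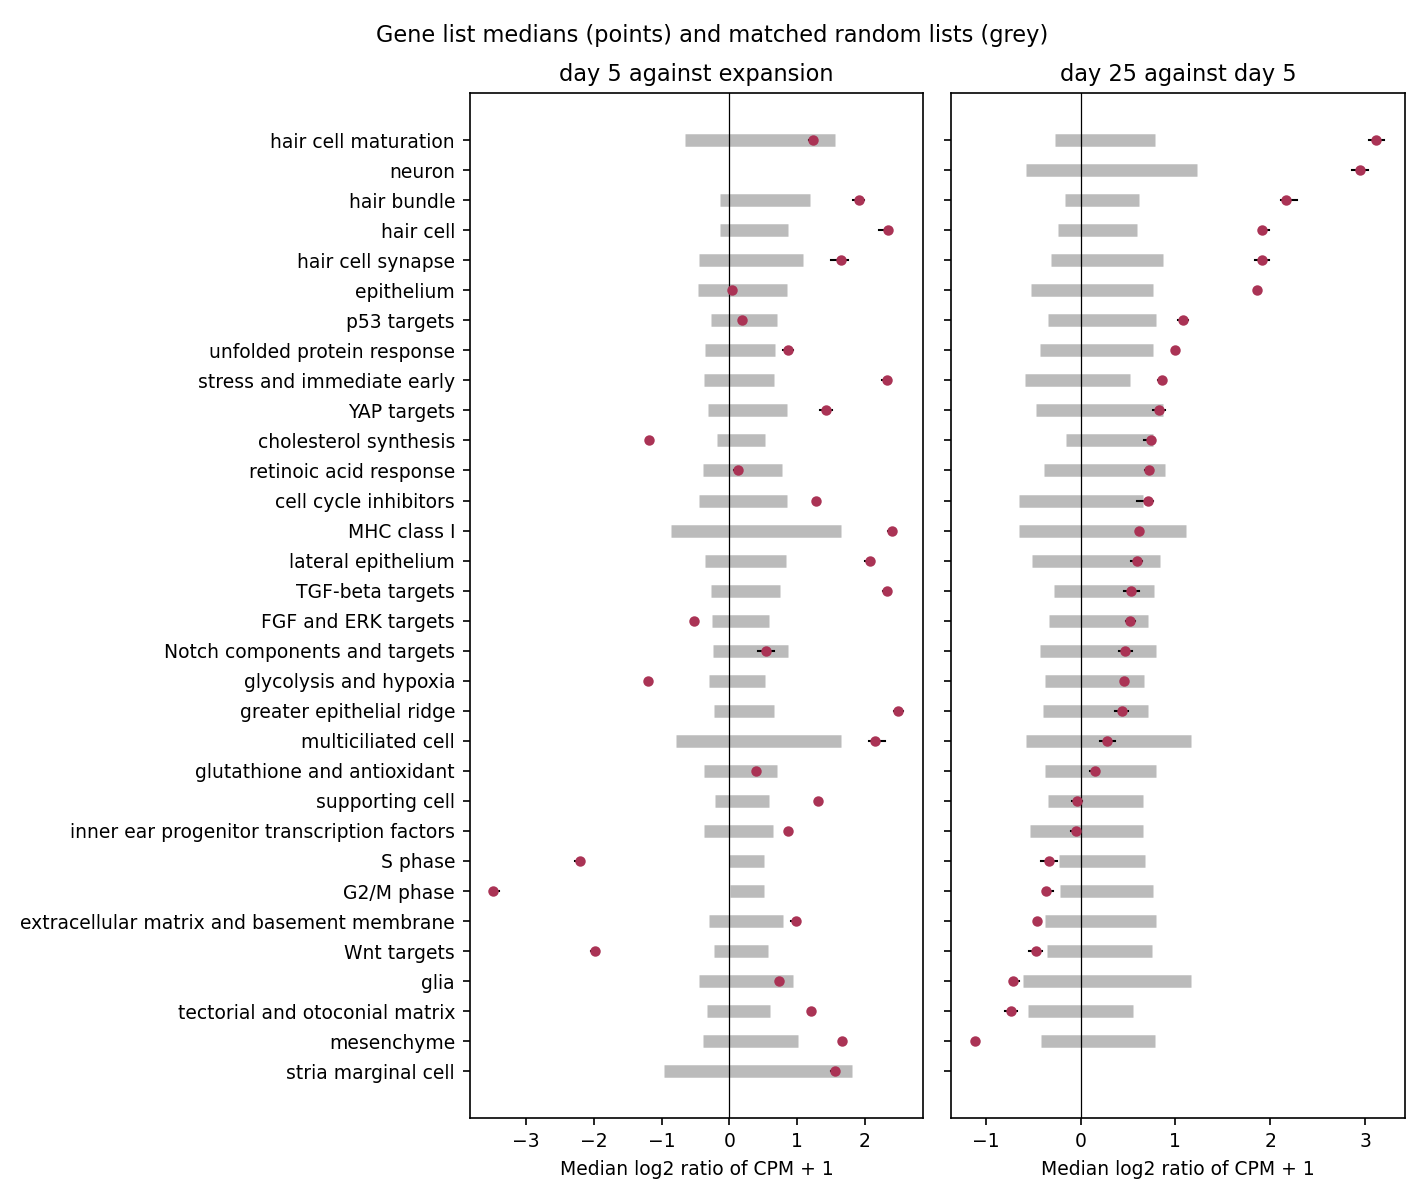
Median log2 ratio of CPM + 1 of each gene list for day 5 against expansion (left) and day 25 against day 5 (right); points are list medians, black lines their range under counting error, and grey bars the central 95% of random lists of matched expression. G2/M phase genes lie at -3.48 on the left and hair cell maturation genes at 3.11 on the right.

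**Figure D2:**
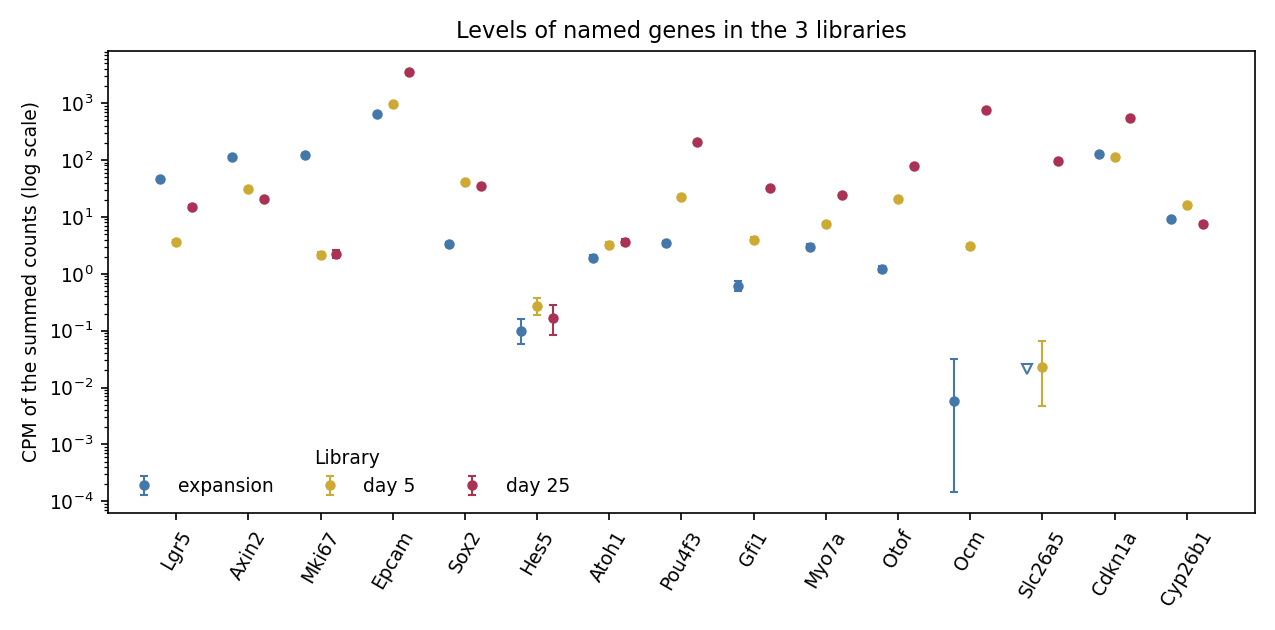
Level of selected genes in the 3 libraries, in CPM on a log axis; points are levels, lines 95% counting intervals, and the open triangle marks 0 counts, drawn at the upper Poisson bound. Mki67 lies at 122 CPM in expansion and at 2.11 and 2.23 CPM on days 5 and 25, and Pou4f3 at 3.54, 22.1 and 205 CPM.

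Shares of cells with a UMI of a marker were compared after each cell was thinned to 2000 UMIs, which left out 2757, 1797 and 372 shallower cells. The cells left out were not a random part (clusters are described below). Day 5 cluster 17, which held 20 of 24 hair cell markers, had a median of 1548 UMIs, so most of it was left out. Day 25 cluster 16, also hair cell-like, had a median of 3644.5 UMIs and mostly stayed. The thinned day 5 shares of Pou4f3 and Otof therefore lack most of cluster 17. Expansion cluster 7, led by cell division genes, had a median of 1621 UMIs. Pou4f3 was found in 0.522% of expansion cells (0.432 to 0.625), 2.60% of day 5 cells (2.32 to 2.91) and 22.0% of day 25 cells (21.0 to 23.1), and Otof in 0.245%, 2.27% and 12.5%. Lgr5 was found in 6.34% (6.03 to 6.67), 0.689% (0.546 to 0.858) and 2.32% (1.95 to 2.74), Sox2 in 0.593%, 5.54% and 5.87%, and Epcam in 57.0%, 56.3% and 78.2%. Atoh1 was found in 0.388%, 0.436% and 0.745%, Myo7a, the gene of a bundle motor protein, in 0.557%, 0.802% and 4.25%, and Mki67 in 15.4%, 0.392% and 0.399%. As background served cells high in the mesenchymal factor Pou3f4 and low in Epcam, which made up 28.2%, 38.2% and 10.5% of cells and had median depths of 3995, 5855.5 and 7357 UMIs against 4558, 5832 and 8482 in all cells. In them Pou4f3 was found in 0.0744%, 0.404% and 0.786%, Otof in none of 6718 cells, 0.605% and 0.943%, Sox2 in 0.0893%, 0.493% and 0.157%, Atoh1 in 0.0447%, 0.0673% and 0.157%, and Myo7a in 0.372%, 0.224% and 0.315%. These cells were selected for low Epcam, so the Epcam shares have no independent background. Their Lgr5 share was 0.804% in expansion, 0.314% on day 5 and 0 of 636 cells on day 25, up to 0.578%. For Mki67 the hair cell-like cells served as background, with 4.55% in expansion, 0 of 214 cells on day 5 and 0.555% on day 25. Their median depths were 5317, 11822.5 and 8275 UMIs. The day 25 share of all cells was thus within the background. On day 5, 214 background cells were too few to place the share of 0.392% above it. Unthinned, the shares in expansion, day 5 and day 25 were 0.965%, 5.53% and 30.3% for Pou4f3, 0.468%, 5.06% and 24.4% for Otof, 18.7%, 3.03% and 10.7% for Lgr5, 1.94%, 15.01% and 21.4% for Sox2, 0.671%, 1.58% and 2.65% for Atoh1, 1.78%, 2.58% and 14.4% for Myo7a, 67.6%, 62.6% and 85.5% for Epcam, and 32.5%, 1.18% and 1.73% for Mki67.

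Cells with at least 3 UMIs of the S phase or of the G2/M list made up 84.4% of thinned expansion cells (84.0 to 84.9), 39.3% of day 5 cells (38.4 to 40.2) and 38.4% of day 25 cells (37.1 to 39.6). The S phase list alone gave 53.1%, 7.75% and 6.05%, and the G2/M list 78.6%, 34.9% and 34.1%. Hair cell-like cells, of which few held a Mki67 UMI, gave 71.4%, 35.05% and 36.005%, and free RNA may add to such calls, so no share of dividing cells is read from them. Top2a, the gene of a topoisomerase of dividing cells, was at 241, 5.48 and 2.59 CPM in the 3 libraries.

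**Figure D3:**
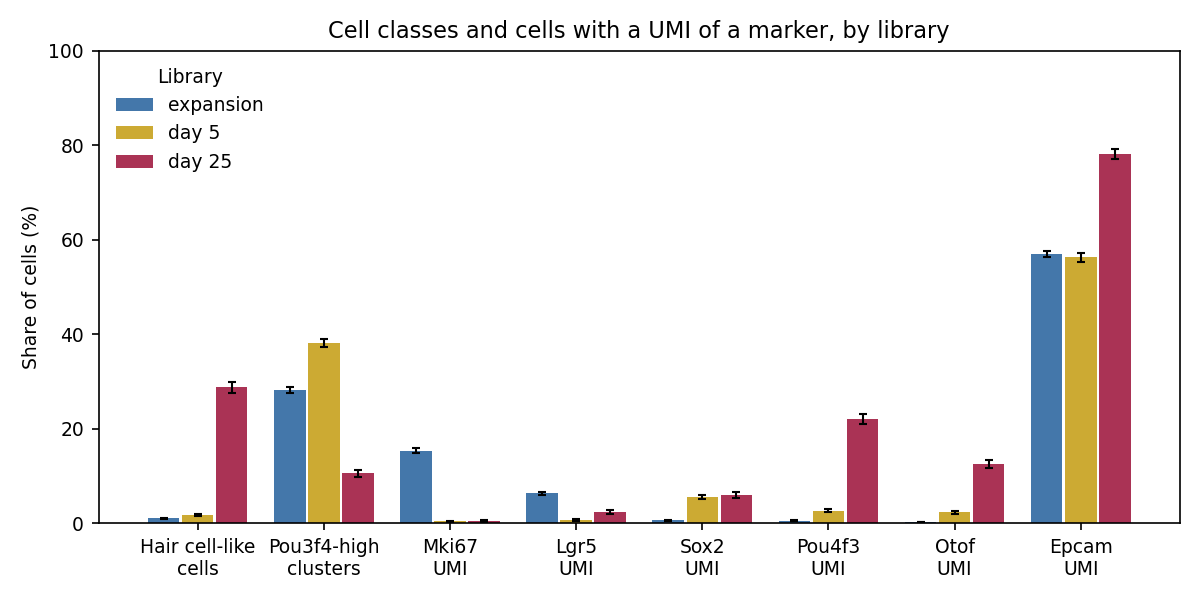
Percent of all kept cells in the hair cell-like and Pou3f4-high classes of the joint clustering, and percent of cells thinned to 2000 UMIs with a UMI of each of 6 markers, in each library; bars are shares and lines exact Clopper-Pearson 95% intervals. Pou4f3 reaches 22.0% and the hair cell-like class 28.7% on day 25, against 0.522% and 0.988% in expansion.

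Joint clustering without integration gave 39 clusters, most of them made up of cells of 1 library, and clusters were named from the marker lists. Hair cell-like cells were 0.988% of expansion cells (0.870 to 1.12; 249 cells, nearly all in cluster 27), 1.64% of day 5 cells (1.43 to 1.87; 218 cells, nearly all in cluster 29) and 28.7% of day 25 cells (27.6 to 29.9; 1765 cells, nearly all in clusters 14 and 16). With the clusters left out by the naming rule counted, the day 5 share was 6.64% and the day 25 share 29.4%. With each library clustered on its own, they were 6.62% and 17.3%, and both depended on which clusters the naming rule left out. Cluster 17, with 4.92% of day 5 cells, was not counted because its leading genes held more multiciliated than hair cell markers, and cluster 36, with 0.651% of day 25 cells, was not counted either. Within hair cell-like cells thinned to 2000 UMIs, Pou4f3 was found in 46.4%, 66.8% and 75.5%, Otof in 23.6%, 62.15% and 41.6%, and Atoh1 in 36.4%, 14.95% and 2.53%. Supporting cell-like cells were 12.3% of day 25 cells (758 cells, cluster 15). No cluster of expansion or day 5 got that name, so the class could not be compared between libraries. The lack of a name does not show that such cells were absent. Day 5 cluster 4 held 3 supporting cell and 3 lateral epithelium markers and was named for the lateral list, the shorter one (10 genes against 20). Its Sox2 level was 102.6 CPM, against 67.5 CPM in cluster 15, which held 5 supporting cell markers. No name was reached for 99.0%, 15.98% and 21.2% of cells.

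Hair cell-like cells of day 25 (mainly clusters 14 and 16) were compared with those of day 5 (mainly cluster 29). Day 25 included its shallow cluster 16 (751 cells), while day 5 left out its shallow cluster 17 (653 cells). Cluster 17 held 20 of 24 hair cell markers, with Otof at 211 CPM against 582 CPM in cluster 29. Differences may therefore rest in part on which clusters were counted and not on time in culture. Of the hair cell maturation genes, 11 of 16 were higher on day 25, while Atoh1 and 5 of 7 multiciliated cell genes were lower. Ocm was at 2964 against 69.1 CPM, 42.9-fold higher (37.9 to 48.7). Atoh1 was at 13.8 against 96.8 CPM, 7.03-fold lower (5.96 to 8.29), with Pou4f3 at 799.6 against 597 CPM and Gfi1 at 124 against 111 CPM. Of 7083 genes, 1210 were higher and 608 lower, with a median of all genes of 0.20; with cluster 16 left out, 1434 of 7213 were higher and 689 lower.

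Beside the 11 higher maturation genes 1 was lower (median 1.54, above the range of random lists). Slc26a5 was at 381 CPM against 3 UMIs, a ratio of 463 (158 to 2247); the calcium-activated potassium channel gene Kcnma1 was 18.9-fold, the nicotinic receptor gene Chrna9 7.14-fold, Kcnn2 2.97-fold, Lmod3 2.89-fold and Kcna10 2.68-fold higher, and Tbx2, an inner hair cell factor, was 2.25-fold lower. The 28 bundle genes split 6 higher to 4 lower (median 0.08): Tmc1 was 16.8-fold (12.5 to 23.1), Ush1c 4.84-fold, Grxcr2 3.89-fold and Ptprq 3.06-fold higher, and Fscn2 3.48-fold, Whrn 3.27-fold, Myo7a 2.48-fold and Cdh23 2.12-fold lower. Synapse genes split 4 to 2 of 13, with Slc17a8 19.1-fold (14.003 to 26.8), Snap25 5.69-fold, Cabp2 2.32-fold and Pclo 2.22-fold higher, Cplx1 2.28-fold and Rims2 2.06-fold lower, and Otof at 304 against 583 CPM. The hair cell list was lower in 9 of 24 cases and higher in 3 (median -0.77).

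Besides Slc26a5, the genes with the largest differences toward day 25 included Spp1 (4127 against 9.05 CPM, 456-fold), Cdh13 (233-fold), Atf3 (128-fold), Pxdc1 (108-fold), Cd83 (at least 136-fold, with no UMI on day 5), Cxcl10 (346 CPM against 1 UMI, a ratio with an interval of 226 to 49799.8) and Ifit1 (154 CPM against 2 UMIs, 77.6 to 2319). R3hdml (114-fold), Col2a1 (55.8-fold), Otor (45.6-fold), Fam81b (38.4-fold), Tmem91 (30.95-fold), the hair cell marker Ccer2 (20.3-fold), Grp (18.7-fold) and the chaperone gene Cryab (16.6-fold) were lower. By list, supporting cell genes were higher in 9 of 14 cases and lower in 5 (median 1.46), epithelial genes higher in 5 of 8 (median 1.97), and multiciliated cell genes lower in 5 of 7 (median -2.21), mesenchyme genes in 5 of 6, and matrix and basement membrane genes in 4 of 7. Notch genes split 3 higher to 5 lower of 8 (median -1.71) and tectorial and otoconial matrix genes 2 higher to 6 lower of 10 (median -1.89). Stress genes were higher in 4 of 11 cases, unfolded protein response genes in 4 of 10, p53 targets in 3 of 9, with 1 lower, and MHC class I genes in 4 of 4. The epithelial list had a similar median, 1.86, between the whole libraries. Genes abundant in other cells of a library, such as Col2a1 and Otor on day 5 and epithelial genes on day 25, have levels in this class that include RNA of those cells to an unknown extent.

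**Figure D4:**
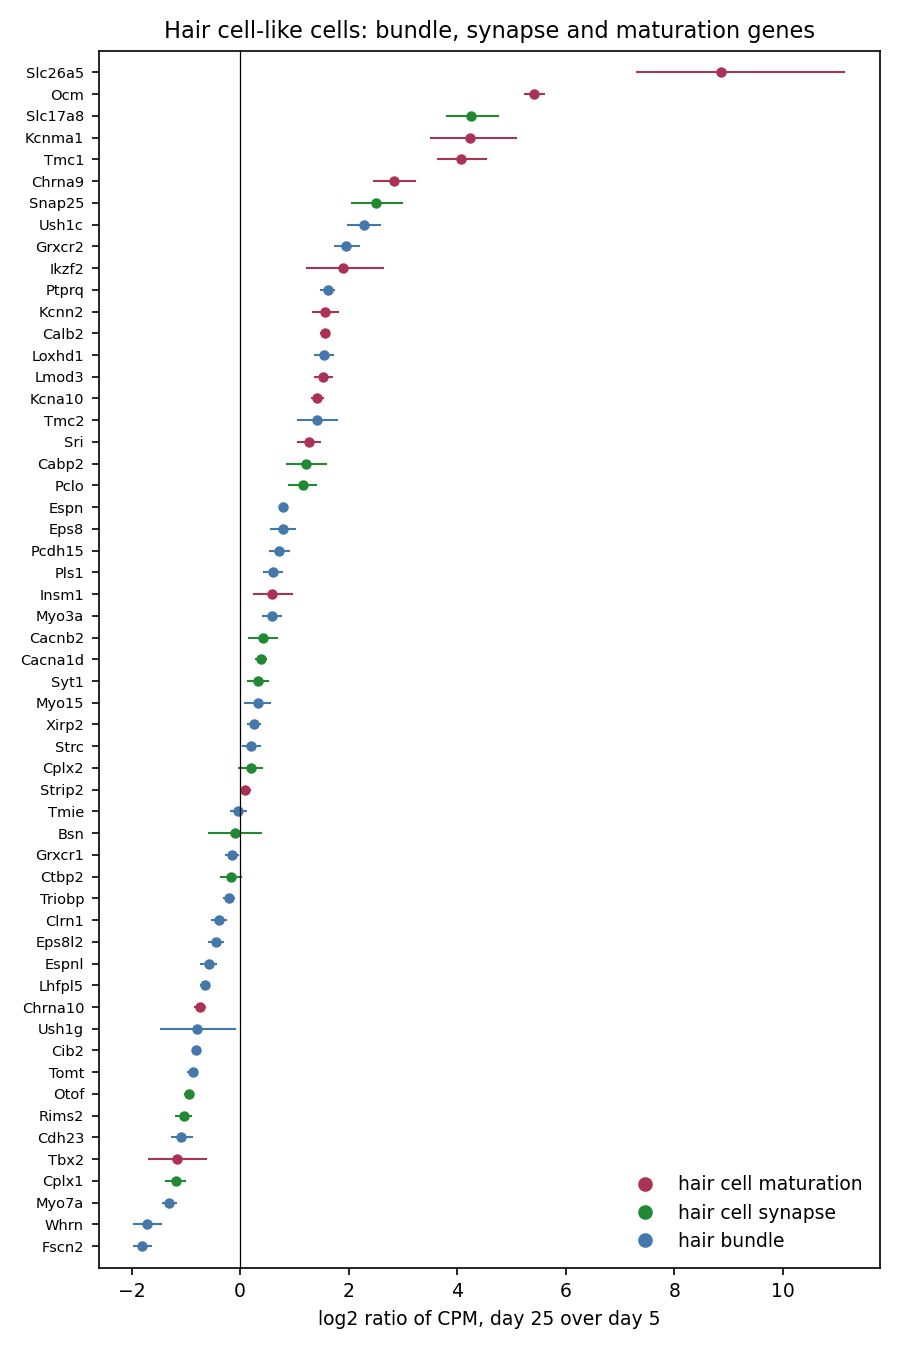
Log2 ratio of CPM, day 25 over day 5, of hair bundle, synapse and maturation genes in hair cell-like cells; points are genes coloured by list (maturation where a gene is in that list and another) and lines are 95% counting intervals. Ocm, 42.9-fold higher, lies at the upper end, and Otof and Myo7a lie below 0.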

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

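Leaving out the Pou3f4-high cells, counting clusters that the naming rule had left out, and leaving out the day 25 hair cell-like cluster of low depth were chosen after the data had been seen; the other alternatives were written before. No paired analysis was possible because each group held 1 library and nothing links cells across libraries.

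The split of genes depended on scaling. TMM gave 636 genes higher and 934 lower for day 5 against expansion, 915 and 774 for day 25 against day 5, and 1234 and 1608 for day 25 against expansion. Median of ratios gave 619 and 961, 984 and 699, and 1275 and 1565. With no filter beyond 1 CPM, more genes were counted, and 2366 were higher and 1040.0 lower, 2529 and 960.0, and 4268 and 1298. The other 44 of 62 alternative counts stayed within 1.5 times the reported count.

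With the Pou3f4-high cells left out, 5 values changed sign: for day 25 against day 5, Npy (0.22), the S phase median (0.0093), the G2/M median (0.045) and the Wnt target median (0.24), and for day 25 against expansion, Pdgfrb (-0.089). The Pou3f4-high cells were 38.2% of day 5 and 10.5% of day 25, and the cause was not tested further. Of 576 alternative list medians, 343 moved beyond their counting range, 3 reversed and 230 stayed within it, and with TMM some medians inside the range of random lists changed sign; of 4751 values of named genes, 2860 moved, 2 reversed and 1889 stayed.

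The share of cells in S or G2/M depended on depth and on the number of UMIs asked for. In expansion it was 64.2% at 1000 UMIs, 95.4% without thinning, 85.7% with doublets kept and 65.3% at 5 UMIs or more of a list. On day 5 it was 10.8%, 82.2% without thinning and 8.25% at 5 UMIs, and on day 25 it was 9.90%, 88.2% and 7.05%. In each of these settings expansion was highest. Hair cell-like cells of day 5 were 6.64% with the clusters left out by the naming rule counted and 6.62% with each library clustered on its own, which on day 25 gave 17.3%. In the clustering of each library on its own, a shallow day 5 cluster of 653 cells was named by the rule, and day 25 clusters of 509 and 203 cells with 9 and 5 hair cell markers were not; 12 of 15 alternatives stayed within the counting interval. Of 96 differences of marker shares between libraries, 52 moved, 44 stayed and 0 reversed, where only shares with separate intervals could count as reversed.

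Supporting cell-like cells were not compared under any alternative, since the naming rule gave that name to day 25 cells only. Depth sets a limit on the hair cell-like comparison, as the day 5 cells held 3645794 UMIs, a floor of 0.823 CPM.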

Other observations

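The tests of empty droplets, of the mix of cell types, of the Cell Ranger version and of Paneth cell transcripts, and the comparisons of classes given first, were chosen only after the result had been seen.

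Hair cell-like cells of day 5 (mainly cluster 29) differed from those of expansion (mainly cluster 27) in bundle and synapse genes. Bundle genes were higher in 20 of 28 cases and lower in 1 (median log2 ratio 1.78), synapse genes higher in 8 of 13, and maturation genes higher in 7 of 14 and lower in 2. The bundle and synapse lists were also higher between the whole libraries, with medians of 1.91 and 1.64. Lists of other cell types were higher in this class as well: multiciliated cell genes in 6 of 7 cases (median 1.72) and lateral epithelium genes in 4 of 6, with 1 lower (median 2.04). Myo3a, the gene of a bundle motor, was 36.6-fold higher (14.2 to 135), Calb1 35.2-fold, Kcna10 22.0-fold and Otof 4.90-fold higher, and Ocm, with no UMI in expansion, at least 36.6-fold. Atoh1 was lower, at 96.8 against 193 CPM. S phase genes were lower in 25 of 37 cases and G2/M genes in 33 of 45, as were 12 of 14 Wnt targets and 12 of 15 glycolysis genes. Epithelial genes were lower in 4 of 7 cases and higher in none, with a median of -2.32. The S phase, Wnt target and glycolysis lists also fell between the whole libraries, with medians of -2.20, -1.98 and -1.20, so these falls were not particular to hair cell-like cells.

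Pou3f4-high cells of day 5 had more of the chemokine transcript Ccl2 (1143-fold), the calcification inhibitor Mgp (967 against 6.41 CPM), Bgn (166-fold) and Col2a1 (41.9-fold) than those of expansion, and Otor reached 8157 against 1683 CPM. All 12 TGF-beta targets were higher (median 2.94), and 42 of 50 G2/M genes were lower. On day 25 these cells had more Saa3 (198-fold), Apod (4247 against 73.35 CPM), Lcn2 (52.5-fold) and Mt1 (41.1-fold), and less Col2a1 (15.8-fold) and Otor (2.14-fold), than on day 5. The class was made up of different clusters in each library, and its day 25 clusters differed. Otor was at 2268 CPM in cluster 22 (398 cells) and 6498 CPM in cluster 28 (231 cells), against 5843 to 8313 CPM in the day 5 clusters. Saa3, Apod and Lcn2 were leading genes of cluster 22 and not of cluster 28, so cluster 22 may carry these differences.

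Hair cell-like transcripts were found in clusters of very different depth within a library: on day 25 the median cell of cluster 16 held 3644.5 UMIs with 1.39% mitochondrial counts, against 12140 UMIs and 10.9% in cluster 14, and on day 5 cluster 17 held 1548 UMIs and 1.503%, against 12110 and 9.33% in cluster 29. This was not particular to hair cell-like cells. Expansion cluster 7 (1621 UMIs, 2.44%) and day 5 cluster 24 (1375 UMIs, 2.38%) were also shallow with few mitochondrial counts. The nuclear RNA Malat1 was at 1598 CPM in cluster 7, against 8270 to 22019 CPM in the other expansion clusters. In cluster 24 it was at 7301 CPM, against 38079 CPM in day 5 cluster 3. Shallow clusters 12, 19, 26 and 36 instead had 7.59%, 7.41%, 13.1% and 8.14% mitochondrial counts. As a test of empty droplets, abundant genes of the other cells lay at a median log2 ratio to the whole library of -4.22 in cluster 16 (190 genes) and -2.99 in cluster 17 (118 genes). Free RNA of the whole library would have kept them near 0. However, both clusters had stood out for hair cell markers at least 4-fold over all other cells, so low values were likely beforehand. The test therefore decides little, and droplets with free RNA of hair cells were not tested. Loss of nuclear RNA cannot be told apart from other causes: the median of long noncoding RNA genes minus that of protein-coding genes was 0.57 (-0.10 to 0.81) on day 25 and 0.52 (0.34 to 0.70) on day 5, above the bound of -0.5 set against it, but the bound was weak since annotated long noncoding genes mix nuclear and cytoplasmic RNAs and went both ways (30 lower and 10 higher of 84, 15 lower and 6 higher of 81). Single nuclear RNAs, picked with values seen, were lower in the shallow clusters, with Malat1 20.97-fold, Xist 52.6-fold, Kcnq1ot1 28.4-fold and Miat 28.5-fold lower in cluster 16, and 6.22-fold, 2.62-fold, 13.6-fold and 56.4-fold lower in cluster 17. Not all such genes differed as much: Neat1, also a nuclear RNA, was 2.54-fold lower in cluster 16 and had 3 against 12 UMIs in clusters 17 and 29, and the protein-coding gene Otof was 2.76-fold lower in cluster 17, more than Xist there. No biological explanation was tested.

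Near-identical copies of ribosomal protein genes took different shares of the counts: Gm10260 held 4.13% of the counts of Rps18 and itself in expansion, 38.7% on day 5 and 7.98% on day 25, and Gm10076 with Rpl41 held 5.36%, 15.8% and 3.47%. The pair Rps18 and Gm10260, as a share of ribosomal protein counts, differed 1.43-fold between expansion and day 5. That was below, but close to, the bound of 1.5-fold set for reads of a gene counted on its copy. In CPM the pair itself stood at 4396 in expansion and 2122 on day 5, so it was alike only relative to ribosomal protein counts. Between expansion and day 5, a different mix of cells is argued against, as the lowest day 5 cluster was 7.98-fold above the highest expansion cluster, and so is the Cell Ranger version alone, as the 9.37-fold difference lay between libraries of the same version. For day 25 a mix of cells stays open, since its clusters ranged from 3.02% to 13.5% and the lowest was at 0.648 times the highest of expansion (4.66%). What set the shares in each library remains open, and no biological explanation was tested.

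The alpha-defensin genes Defa21 and Defa22 (chromosome 8, 21025545 to 21026516 and 21162277 to 21163249 in GRCm38) stood at 2528 and 2510.3 CPM in the hair cell-like cells of expansion, 1.495 and 1.57 CPM in its other cells, 0 UMIs on day 5 and 10 UMIs on day 25. Paneth cells or their RNA are argued against, since other Paneth cell transcripts summed to 0.0500% of the pair. A few stray cells holding all counts are argued against too, since 55.0% of 249 cells (48.6 to 61.3) held a UMI, against 1.20% of 24941 other expansion cells. That share was far above the 10% set for this explanation, though its interval reached below the 50% set against it. The median of the 249 cells held 1 such UMI and the highest 519. The 10 cells with the most UMIs nevertheless held 43.1% of them. Reads of a gene outside the family cannot be told apart: the closest gene not named as an alpha-defensin, Gm15293, shared 9.26% of 31-base words of the transcript ends, between the bounds of 1% and 10%, and had 0 CPM in these cells. It shared as many as Defa34 and Defa5 and may itself be a paralog, since it was placed outside the family by its symbol only. Which of the paralogs was read is uncertain, as Defa21 shared 77.04% of its words with Defa22, and an effect of the expansion medium stays open, untested.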
